A study of Bos taurus with 32 samples.

How the data were processed

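RNA from pools of 15 bovine embryos produced in vitro was sequenced at 4 stages of preimplantation development. Embryos were cultured with a mix of 3 cytokines, FGF2, LIF and IGF1 (abbreviated FLI), or without it (control). Each of the 8 groups, a treatment at a stage, holds 4 libraries, which makes 32 in all. Per the labels, RNA was isolated with a PicoPure kit and amplified with the SMART-Seq v4 low-input kit, which primes on poly(A) tails. The labels do not say whether replicates of a stage came from separate cultures, so the p-values measure the spread between these pools.

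The authors deposited 1 table per stage. Per the submitters' processing notes, reads were checked with FastQC, aligned with HISAT2 to the build ARS-UCD1.2, counted per gene with featureCounts and analysed with edgeR; versions, strand setting and gene filter are not given in the sources used here. In the deposited tables the values are a normalised signal per gene and library, reads divided by a scaled library size, so the unit used here is signal. Within every column 100% of values were whole multiples of the smallest positive value, within a tolerance of 0.001, and division by that value gave whole reads. The sums of these recovered reads are the depths given below. The deposited tables also hold the authors' log2 fold changes (unit log2), the likelihood ratio as a score, and p-values with false discovery rates (unit p_value), per the file headers. The authors' log2 fold change is control minus FLI, since its sign was opposite to FLI minus control for 98.38% of 1851 genes at the morula stage and 100% of 731 at the blastocyst stage.

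The comparisons, the tests, the 30 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The planned test, the edgeR quasi-likelihood test, needs counts, and the deposited values are scaled. After this was seen, the test reported was changed to limma (empirical Bayes with trend and robust options) on log2(value + 1). It took genes with a mean of at least 1 over the 8 libraries of a stage. Fold changes on this scale understate changes of genes near or below 1. edgeR, limma-voom and DESeq2 on the recovered reads are alternatives. The recovered reads allowed the planned edgeR test too, run without its robust option. It called more genes than limma between control stages and in some sets of morula libraries, and fewer in blastocysts with all libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The interaction of treatment with stage and the comparisons of controls between stages used recovered reads of the 14225 genes listed in all 4 tables, with a joint TMM normalisation, log2(CPM + 1) and limma. The 16 controls went into 1 fit, so that each pair of stages borrows the spread of all of them. Stages are separate collections, so stage and collection cannot be told apart.

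Gene lists were tested with camera, a test of whether the members of a list move relative to the other genes, at a preset correlation between genes of 0.01, for lists with at least 5 members tested. Adjusted p-values are over the lists of a comparison. Estimated correlations and fry, which asks whether members move on balance one way, are alternatives. Counts of members called are given over all genes tested and adjusted over the list alone. The lists cover FGF-ERK response, LIF-STAT3 response, FOXO targets, receptors and ligands of the added cytokines, epiblast, trophectoderm and hypoblast markers, embryonic genome activation, maternal transcripts, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins and ribosome biogenesis. They also cover cholesterol, fatty acids, antioxidants, unfolded protein response, heat shock, p53, S phase, mitosis, DNA methylation and histone enzymes, imprinted genes, extracellular matrix, interferon-stimulated genes and amino acid transport. Markers of cumulus, sperm, and blood, immune or endothelial cells stand for other cells that the pools could hold. Symbols and coordinates are those of the deposited tables.

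Named genes were, per stage, the 12 largest rises and falls among called genes with a symbol, a mean of at least 1 and no overlap between groups. Where fewer than 5 qualified, the 5 with the smallest p were named, as values. Each list contributed up to 4 called members, or up to 2 as values. Between control stages the 5 largest rises and falls were named, with members of the maternal, genome activation and lineage lists. The same rule was applied to the authors' deposited table and, after the data were seen, without shallow libraries.

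Measures per library were compared with a two-sided exact permutation test of the difference of means over all 70 arrangements of 8 libraries, whose smallest p is 0.0286. They were genes detected at 1 CPM, the share of reads in mitochondrially encoded genes, the share in the 100 most abundant genes and total reads, adjusted over 16 tests. After the data were seen, 2 measures were added, adjusted over 8 tests. They were the share of reads in 2 loci that hold rRNA fragments, and the median log2 level of the shortest 25% of genes minus that of the longest 25%. Results within the libraries with an rRNA-fragment share of at least 0.2% are given beside those of all libraries where both groups keep at least 2 libraries, and at the blastocyst stage, with 1 FLI library, only as counts and changes of sign.

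Depth was 12.4 to 89.2 M reads at the 4-6 cell stage and 7.01 to 50.6 M at the 9-16 cell stage. Of 8 libraries, 7 had 11.6 to 114 M reads at the morula stage and 7 had 62.6 to 169 M at the blastocyst stage. Morula control replicate 4 had 83409 reads and blastocyst control replicate 6 had 2995. A count of 0 there allows up to 3 reads, a level of 36.0 CPM and 1002 CPM. Elsewhere it allows at most 0.428 CPM, for counting error only. These 2 libraries were kept, as planned. Every count was also made without them, a choice made after the depths were seen, and means of the remaining controls are called deep.

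Data were simulated with the depths of each stage, the same spread for every gene and no difference between libraries beyond depth and group. Recovery in the real data can therefore be lower. Of simulated genes changed 8-fold, 98.5%, 100%, 62.1% and 6.1% were recovered at the 4 stages in order. Of those changed 4-fold, 65.7%, 91%, 25.4% and 1.5% were. Without the shallow library, 8-fold recovery was 100% at the morula and the blastocyst stage. Between control stages it was 12.1%, 13.6% and 0% with all libraries, and 98.5%, 100% and 92.4% without the shallow ones. FLI and control share all 4 replicate numbers at each stage but the morula, where they share 2. At the 4-6 cell stage, libraries with the same number deviated together from their group means, with correlations across genes of 0.924, 0.815, 0.473 and 0.689, so fits with the number as a block were run as an alternative. Other alternatives were filters, a pseudocount of 0.1, RLE scaling, thresholds, other tools, all libraries in 1 fit, leaving out each library, and covariates. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A table pairing locus tags with symbols matched none of the identifiers and was not used here. Values of 2 single genes between control stages are not reported here.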

Results

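The data are gene expression profiles of bovine preimplantation embryos cultured with FGF2, LIF and IGF1 or without them, at the 4-6 cell, 9-16 cell, morula and blastocyst stages. Each stage has 4 FLI and 4 control libraries. FGF2 signals through FGF receptors to ERK, LIF through LIFR and IL6ST to STAT3, and IGF1 through IGF1R to AKT. The series asks how the mix alters the transcriptome as the embryo activates its genome, compacts and forms its first lineages. Values are the deposited signal per gene, as mean ± SD with n = 4 per group unless stated. In comparisons across stages they are jointly normalised CPM.

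Depth was 12.4 to 89.2 M reads at the 4-6 cell stage, 7.01 to 50.6 M at the 9-16 cell stage, 11.6 to 114 M in 7 morula libraries and 62.6 to 169 M in 7 blastocyst libraries. Morula control replicate 4 held 83409 reads and blastocyst control replicate 6 held 2995. The share of reads from mitochondrially encoded genes, a measure tied to cytoplasmic content and library preparation, was 2.94% ± 1.10 in FLI morulae and 7.16% ± 3.60 in control morulae (exact permutation p = 0.0286, the smallest it can give; adjusted p = 0.229). Without control replicate 4 the control mean was 5.40% ± 0.966. Blastocyst libraries held 148 ± 25.4 M reads with FLI and 64.0 ± 46.3 M without it (exact permutation p = 0.0286, adjusted p = 0.229). Genes detected at 1 CPM differed by 60.3, -14.5, 1568 and 2617 genes (FLI minus control) at the 4 stages in order, and the smallest adjusted exact permutation p was 0.305, at the morula stage. With single libraries left out these ranged from 23.6 (control replicate 7) to 118 (control replicate 6), from -72.8 (control replicate 13) to 18.2 (control replicate 11), from 572 (control replicate 4, the shallow one) to 2079 (control replicate 7), and from -279 (control replicate 6, the shallow one) to 3658 (control replicate 8). The share of reads in the 100 most abundant genes was 18.3% to 27.4% in FLI groups and 19.1% to 28.6% in controls, with adjusted exact permutation p-values of 0.849 to 0.876. Fragments of rRNA took 3.33% ± 2.60 of reads in FLI morulae and 0.570% ± 0.876 in control morulae (exact permutation p = 0.143, adjusted p = 0.381). In blastocysts they took 0.0980% ± 0.193 with FLI and 0.703% ± 0.378 without it (exact permutation p = 0.0571, adjusted p = 0.343).

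The first comparison asks what the cytokines change before the embryo's own genome becomes active. At the 4-6 cell stage no gene was called between FLI and control embryos, and lists moved little. As lists at a preset correlation, transcripts of cytosolic ribosomal proteins and of nuclear-encoded oxidative phosphorylation were slightly lower with FLI, while those of the mitochondrial genome, hypoblast markers and glycolysis were slightly higher. All 5 calls ended with an estimated correlation (adjusted p = 0.188 to 0.927), and that of hypoblast markers with the replicate number as a block (0.0524). The difference with the smallest p was in LAMA1, a laminin chain of basement membranes, at 4.26 ± 1.82 with FLI and 1.44 ± 0.724 without it.

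Lists gave small shifts in this stage, and no member of any list was called over all genes or adjusted over the list alone. Of 76 ribosomal protein genes, 75 had a negative fold change, with a median log2 of -0.27 (camera adjusted p = 2.31e-09; adjusted p = 0.927 with an estimated correlation). Of 73 oxidative phosphorylation genes, 12 had a positive fold change and the median was -0.21 (camera adjusted p = 0.0103; adjusted p = 0.927 with an estimated correlation). Of the 13 mitochondrially encoded genes, 12 were positive, median 0.21, among them COX1 of complex IV at 857 ± 187 against 525 ± 148 (camera adjusted p = 6.32e-06; adjusted p = 0.618 with an estimated correlation). Of 19 hypoblast markers, 14 were positive, median 0.16 (camera adjusted p = 0.000854; adjusted p = 0.188 with an estimated correlation). With the replicate number as a block, which the libraries of this stage follow, that list gave an adjusted p of 0.0524. Glycolysis had 16 of 23 members positive, median 0.08 (camera adjusted p = 0.00442; adjusted p = 0.618 with an estimated correlation). LIF-STAT3 response genes and the receptors and ligands of the cytokines (both adjusted p = 0.44), FGF-ERK response genes (0.607) and FOXO targets, which IGF1 signalling restrains (0.619), were not called. Neither were fatty acid genes (0.227), cholesterol and unfolded protein response genes (0.44), genome activation genes (0.506), antioxidant genes (0.607), epiblast (0.619) or trophectoderm markers (0.621). The adjusted p of the other lists lay between 0.874 and 0.942.

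At single genes, limma called 0 of 13385, with 12 at an unadjusted p under 0.05. edgeR, limma-voom, DESeq2 and the edgeR likelihood ratio test called 0 as well, with 22, 35, 53 and 84 at an unadjusted p under 0.05. The 5 smallest p-values belonged to LAMA1 (chromosome 24, 39951775 to 40062824; log2 1.08, SE 0.31), QSOX2 (-0.63, SE 0.20), LONP2 (-0.52, SE 0.18), GIMAP4 (0.69, SE 0.25) and COX1 (0.72, SE 0.26), each with a limma adjusted p of 1. Without control replicate 6, a library with 0.0290% rRNA fragments against 1.49% to 2.10% in the other controls, the sign of the oxidative phosphorylation and ribosomal protein lists turned positive (adjusted p = 3.84e-07 and 0.000397), but FLI replicate 6, which deviates together with it, then stays in. Without both, that is among the libraries with at least 0.2% rRNA fragments, both lists stayed down (adjusted p = 0.0162 and 2.67e-06) and mitochondrially encoded genes, hypoblast markers and glycolysis up (5.61e-10, 0.000254 and 0.000473), while limma called 0 genes (241 at an unadjusted p under 0.05) and 6 lists were called. With the replicate number as a block the oxidative phosphorylation and ribosomal protein lists were down as well (4.36e-11 and 4.58e-27). Without FLI replicate 7 the oxidative phosphorylation list turned positive too, uncalled (adjusted p = 0.815). Other calls ended without FLI replicate 7 (ribosomal proteins, adjusted p = 0.375), FLI replicate 8 (oxidative phosphorylation, 0.807), FLI replicate 9 (oxidative phosphorylation and glycolysis 0.744, hypoblast markers 0.132), FLI replicate 6 or control replicate 9 (mitochondrially encoded genes, 0.245 and 0.191) and control replicate 6 (glycolysis, 0.237). Without FLI replicate 9, 2 lists were called in place of 5.

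The second comparison covers the 9-16 cell stage, when bovine embryos activate their genome. At a preset correlation, LIF-STAT3 and FGF-ERK response genes and DNA methylation and histone enzymes were higher as lists with FLI, and ribosomal protein, oxidative phosphorylation and mitochondrially encoded transcripts lower. All 6 calls ended with an estimated correlation (adjusted p = 0.682). No single gene was called. Uncalled members are given as values: SOCS1, the feedback inhibitor of JAK-STAT signalling, at 99.2 ± 25.4 against 60.7 ± 23.3, KLF4, a pluripotency factor, at 885 ± 152 against 633 ± 207, and MYC at 75.6 ± 23.6 against 47.2 ± 21.1. Of the 6 list calls, 5 ended without control replicate 11, whose rRNA-fragment share was 0.115% against 3.99% to 7.17% in the other 7 libraries.

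Of 23 LIF-STAT3 response genes, 22 had a positive fold change, median log2 0.35 (camera adjusted p = 5.35e-05; 0.0511 among libraries with at least 0.2% rRNA fragments, all but control replicate 11). Of 27 FGF-ERK response genes, 21 were positive, median 0.19, with FOSB, an immediate early factor, at 20.8 ± 4.23 against 13 ± 7.20 (camera adjusted p = 0.00471; 0.491 among those libraries). Of 32 DNA methylation and histone-modifying enzymes, 22 were positive, median 0.20, including the H3K4 methyltransferase KMT2D at 148 ± 26.4 against 91.9 ± 45.9 and the co-repressor TRIM28 at 175 ± 56.8 against 114 ± 31.5 (camera adjusted p = 0.0326; 0.248 among those libraries; 0.107, 0.0619 and 0.105 without control replicate 12, FLI replicate 12 and FLI replicate 13). Ribosomal proteins had 2 of 76 members positive, median -0.59 (camera adjusted p = 1.52e-14; 0.0511 among those libraries), and oxidative phosphorylation 2 of 73, median -0.64 (camera adjusted p = 1.3e-13; 0.0511 among those libraries). Mitochondrially encoded genes had 1 of 13 positive, median -0.48, with ND6 at 158 ± 36.5 against 291 ± 202 (camera adjusted p = 0.000458; 0.00575 among those libraries). Each of these 6 lists had an adjusted p = 0.682 with an estimated correlation, and no member was called over all genes or adjusted over the list alone.

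Not called were mitosis and imprinted genes (both adjusted p = 0.0786), epiblast markers (0.128), antioxidant genes and FOXO targets (0.343), ribosome biogenesis (0.41) and the unfolded protein response (0.444). Maternal transcripts, genome activation genes, trophectoderm markers, glycolysis, p53 targets, blood cell markers, cholesterol and amino acid genes stood at 0.533. Interferon-stimulated and fatty acid genes (0.722), receptors and ligands and heat shock genes (0.737), S phase genes (0.761), hypoblast markers and extracellular matrix genes (0.811) and cumulus cell markers (0.916) were also uncalled. The interferon-stimulated genes ISG15 and IFI27 varied widely among controls, at 17.2 ± 27.1 and 22.3 ± 33.0, against 0.914 ± 0.378 and 2.38 ± 1.81 with FLI.

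limma called 0 of 14139 genes, with 293 at an unadjusted p under 0.05. edgeR, limma-voom and DESeq2 called 0 (606, 480 and 693 at an unadjusted p under 0.05), and the edgeR likelihood ratio test called 8, of which 5 were higher with FLI. The gene with the smallest p was TENT5A, a poly(A) polymerase (chromosome 9, 21497810 to 21504915), at 31.0 ± 7.16 against 13.6 ± 4.62 (log2 1.15, SE 0.27; limma adjusted p = 0.910). It was followed by ZMYND15 (0.97, SE 0.24), MID1IP1, which promotes fatty acid synthesis (1.02, SE 0.27), ZNF774 (-0.88, SE 0.23) and FNDC10 (1.03, SE 0.28). Without control replicate 11, that is among the libraries with at least 0.2% rRNA fragments, limma called 0 genes (263 at an unadjusted p under 0.05) and 1 list was called in place of 6.

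The third comparison asks what differs at the morula stage, when blastomeres compact. At a preset correlation, transcripts of ribosomal proteins and of the respiratory chain in both genomes were lower as lists in FLI morulae, and FGF-ERK and LIF-STAT3 response genes higher. These calls ended with an estimated correlation (adjusted p = 0.637). No single gene was called. ND3, a complex I subunit encoded by mitochondria, stood at 167 ± 45.6 with FLI and 1675 ± 1231 in controls (1108 ± 590 in the 3 deep controls). SOCS3, which LIF induces, was at 33.2 ± 34.3 against 3.17 ± 4.10, uncalled, and ETV4, an FGF-ERK target, at 6.79 ± 1.90 against 1.75 ± 1.42, called only in the deep libraries and adjusted over the list alone. These differences went along with rRNA-fragment shares, given above, and with the level of short against long genes, which was lower with FLI by 0.94 (log2 -0.94; exact permutation p = 0.0857).

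Of 24 FGF-ERK response genes, 20 had a positive fold change, median log2 0.84 (camera adjusted p = 0.0029; 0.000731 without control replicate 4; 0.00557 among libraries with at least 0.2% rRNA fragments). None was called over all genes or adjusted over the list alone with all libraries. In the 7 deep libraries 6 were higher adjusted over the list alone, including ETV4 (log2 1.23, SE 0.31), the phosphatase DUSP5 at 67.8 ± 32 against 22.6 ± 12.7 (n = 3), and FOS at 51.0 ± 20.8 against 21.4 ± 5.45. Of 23 LIF-STAT3 response genes, 20 were positive, median 0.70, among them the survival factor MCL1 at 315 ± 38.0 against 185 ± 29.7 (camera adjusted p = 0.00387; 0.000731 without control replicate 4; 0.000838 in the rRNA set). No member of it was called, adjusted over the list alone, with or without that library. Both lists ended with an estimated correlation (adjusted p = 0.637; 0.56 without control replicate 4). Glycolysis had 21 of 23 members positive, median 0.61 (camera adjusted p = 0.00805; 0.0791 without FLI replicate 7; 0.46 in the rRNA set), amino acid transport 16 of 19, median 0.56 (0.0307; 0.0412 in that set), and fatty acid metabolism 20 of 27, median 0.93 (0.033; 0.407 in that set). Without control replicate 4 their calls ended, at adjusted p = 0.0802, 0.0647 and 0.254, and FABP3, FABP5 and ACADM, which bind or oxidise fatty acids, were then lower adjusted over the list alone. With an estimated correlation the adjusted p = 0.637 for all 10 called lists except fatty acid metabolism (0.765).

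Of 76 ribosomal protein genes, 4 had a positive fold change and the median was -0.86 (camera adjusted p = 5.83e-14; 1.45e-22 without control replicate 4; 1.91e-18 in the rRNA set). In the deep libraries 66 were lower adjusted over the list alone, such as RPS27 at 260 ± 96.1 against 1162 ± 608 and RPS25 at 543 ± 285 against 2509 ± 1203 (n = 4 and 3). Oxidative phosphorylation had 11 of 73 members positive, median -0.94 (camera adjusted p = 7.31e-11; 3.42e-20 without that control; 8.37e-20 in the rRNA set), and 57 were lower adjusted over the list alone in deep libraries, including the electron carrier CYCS at 423 ± 205 against 2344 ± 1157. All 13 mitochondrially encoded genes were negative, median -1.35 (camera adjusted p = 2.24e-08; 0.000731 without that control; 0.0412 in the rRNA set). ND3 alone was lower adjusted over the list alone with all libraries, and 6 members were in the deep libraries, with COX3 at 3991 ± 966 against 18250 ± 7952. Mitosis genes had a median of -0.13 (camera adjusted p = 0.00633; 0.0526 without control replicate 4; 0.0149 in the rRNA set). Each of these 4 lists had an adjusted p = 0.637 with an estimated correlation.

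Maternal transcripts, which the oocyte deposits, had 7 of 36 members positive and a median of -1.12 (camera adjusted p = 9.06e-06; 0.0121 in the rRNA set; 0.637 with an estimated correlation), but without control replicate 4 the median was 0.03 and the adjusted p = 0.566. Among the deep libraries OOEP, of the subcortical maternal complex, was at 14.8 ± 3.88 against 55.8 ± 27.1, and BTG4, which directs maternal mRNA decay, at 7.68 ± 4.70 against 26.8 ± 9.48, both lower adjusted over the list alone. The epiblast list was not called (0.3), although in deep libraries DPPA3, a maternal and germline factor, was lower at 134 ± 40.0 against 344 ± 101 and PRDM14, a pluripotency factor, higher at 226 ± 56.6 against 106 ± 32.4, adjusted over the list alone. FGFR2, a receptor of FGFs, was at 11.2 ± 1.70 against 4.59 ± 1.6 in deep libraries (adjusted p over the list alone 0.0300), and FGFR4 at 349 ± 116 against 146 ± 82.8. Without control replicate 4, extracellular matrix and adhesion genes were called higher (0.0176; 0.56 with an estimated correlation), with CCN1 at 21.2 ± 3.86 against 8.82 ± 0.812, as were interferon-stimulated genes (0.0176), with IRF1 at 58.7 ± 20.9 against 21.4 ± 4.88, and cumulus cell markers (0.0465). Antioxidant genes were called lower (0.0475), with thioredoxin TXN at 162 ± 67.7 against 899 ± 531. All 4 of these calls ended with an estimated correlation (adjusted p = 0.56).

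With all 8 libraries the remaining lists were not called: trophectoderm markers and DNA methylation and histone enzymes (both adjusted p = 0.0663), receptors and ligands (0.071), sperm transcripts (0.072), extracellular matrix (0.0818), S phase (0.158), interferon-stimulated genes and FOXO targets (0.189), and antioxidants (0.252). The others were cholesterol (0.332), hypoblast markers (0.426), unfolded protein response (0.443), genome activation, imprinted genes and cumulus markers (0.663), heat shock (0.675), p53 (0.772), ribosome biogenesis (0.818) and blood cell markers (0.97).

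limma called 0 of 14013 genes, with 1152 at an unadjusted p under 0.05. edgeR and limma-voom called 0 (2959 and 3689 at an unadjusted p under 0.05), DESeq2 579, of which 44 were higher with FLI, and the edgeR likelihood ratio test 864. Without control replicate 4, limma called 0 of 13254 (4203 at an unadjusted p under 0.05, smallest adjusted p = 0.063), edgeR 629 (20 higher with FLI) and DESeq2 2486 (449 higher). Without control replicates 4 and 7, limma called 4620, of which 1847 were higher. The controls then left exceed all FLI libraries in short minus long genes (0.62 and 0.36 against -1.38 to -0.15). Treatment and library preparation cannot be told apart there. In the rRNA set, 3 FLI and 2 controls, limma called 0 (2794 at an unadjusted p under 0.05). The smallest p-values belonged to ND3 (mitochondrial genome, 9823 to 10168; log2 -3.02, SE 0.59), FERMT2, an integrin activator (44.3 ± 8.40 against 165 ± 68.8; -1.79, SE 0.37), the histone H2AC12 (18.3 ± 7.71 against 84.4 ± 39.2; -2.10, SE 0.44), CWC25 (-2.0) and ENSBTAG00000043582 (-3.62), each with limma adjusted p = 0.524. In the deep libraries they were joined by the linker histone H1-4 (chromosome 23, 31796098 to 31796757), at 67.7 ± 6.71 against 406 ± 224 (log2 -2.39, SE 0.39), H2BC18 at 2.81 ± 1.01 against 11.1 ± 0.962, and GUCA1A at 18.8 ± 6.80 against 120 ± 62.9.

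The fourth comparison asks what differs in blastocysts, in which the inner cell mass and trophectoderm have formed. IFI27, an interferon-stimulated gene, was higher in FLI blastocysts, at 8.40 ± 8.51 against 0.268 ± 0.436, a call that ended without the control of 2995 reads. ISG15 and IFI6, of the same list, were at 5.72 ± 7.60 against 0.210 ± 0.199 and 8.10 ± 11.1 against 0.514 ± 0.517, and FLI replicates 6 and 7 carried most of all 3. A pair of overlapping loci that hold rRNA fragments, ENSBTAG00000051364 and bta-mir-2887-2, were lower with FLI. At a preset correlation glycolysis and maternal transcripts were higher as lists, and mitochondrially encoded transcripts lower. All 3 calls ended with an estimated correlation (adjusted p = 0.995), and that of maternal transcripts without the control of 2995 reads (0.164).

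limma called 3 of 12786 genes, with 182 at an unadjusted p under 0.05. They were IFI27 (chromosome 21, 58735482 to 58744443; log2 2.22, SE 0.50, adjusted p = 0.0338), ENSBTAG00000051364 (chromosome 2, 121569848 to 121575674; 1004 ± 1875 against 14040 ± 12250; log2 -5.89, SE 0.92, adjusted p = 2.23e-06) and bta-mir-2887-2 (chromosome 2, 121575106 to 121575160; 1187 ± 2328 against 5743 ± 4320; log2 -6.55, SE 1.36, adjusted p = 0.00903). The groups overlap at each, so they fall outside the naming rule and were named after their values were seen. COL5A2, a fibrillar collagen (4.71 ± 5.74 against 0.0831 ± 0.0960; log2 1.62), and ISG15 (log2 1.72) completed the 5 smallest p-values, both with limma adjusted p = 0.225. Without control replicate 6 limma called 0 of 13029 (2049 at an unadjusted p under 0.05, smallest adjusted p = 0.162), edgeR 0 (2321) and DESeq2 466, of which 85 were higher with FLI. With all libraries edgeR, limma-voom and DESeq2 called 0 (2499, 2066 and 717 at an unadjusted p under 0.05) and the edgeR likelihood ratio test 336. Leaving out control replicate 7, control replicate 8 or FLI replicate 5 left 1 gene each. The call of IFI27 ended without any of 7 libraries, at adjusted p-values from 0.0523 (FLI replicate 5) over 0.153, 0.262, 0.517 and 0.531 (control replicates 8, 6, 5 and 7) to 0.792 and 0.803 (FLI replicates 6 and 7). That of bta-mir-2887-2 ended without 5, at 0.0523 (FLI replicate 5), 0.0917, 0.186, 0.239 and 0.538 (control replicates 7, 5, 6 and 8), and that of ENSBTAG00000051364 without control replicate 6 (0.162). In libraries with at least 0.2% rRNA fragments, of which 1 was FLI, limma called 0 (284 at an unadjusted p under 0.05).

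**Figure D1:**
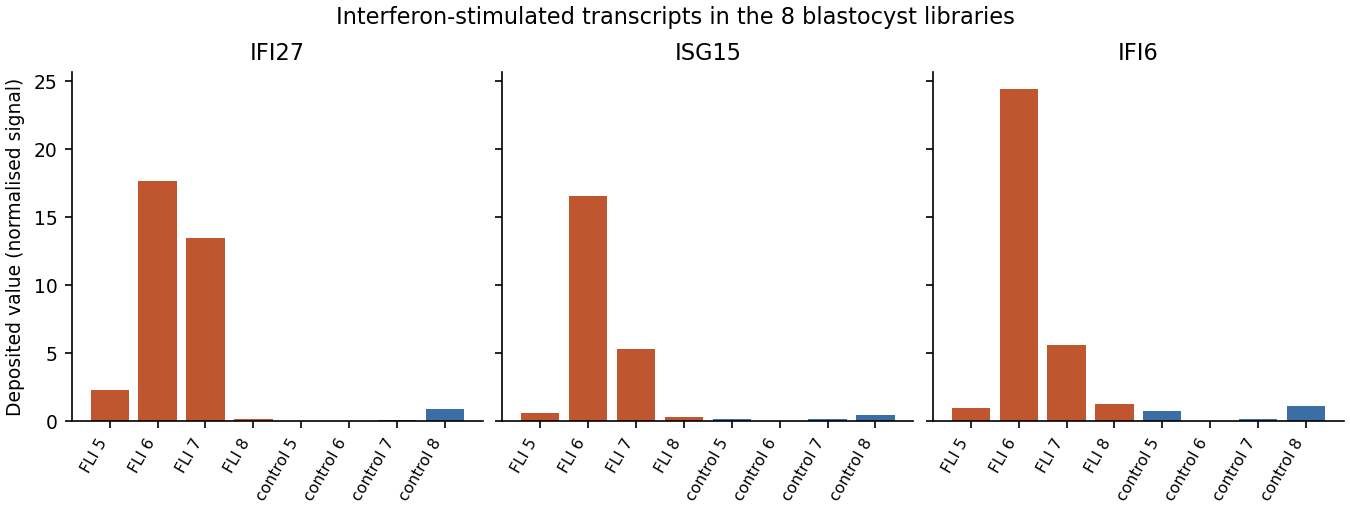
Signal of IFI27, ISG15 and IFI6 in each blastocyst library, bars from 0. FLI replicates 6 and 7 hold 17.7 and 13.5 for IFI27, while FLI replicate 8 holds 0.166 and the control libraries average 0.268.

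Of 17 interferon-stimulated genes, 15 had a positive fold change, median log2 1.09 (camera adjusted p = 0.0418; 0.995 with an estimated correlation; 0.226 and 0.0675 without control replicates 5 and 7). Without control replicate 6 the median was 0.41 and the adjusted p = 0.108. IFI27 was called over all genes, and IFI27, ISG15 and IFI6 adjusted over the list alone, but no member was in either way without control replicate 6. All 25 maternal transcripts were positive, median 1.10, and CPEB1, a regulator of mRNA polyadenylation in oocytes, at 11.7 ± 9.09 against 1.46 ± 1.17, ACCSL at 2.04 ± 0.947 against 0.368 ± 0.567 and ZAR1L at 6.72 ± 6.59 against 1.02 ± 0.824 were higher adjusted over the list alone (camera adjusted p = 0.000545; 0.995 with an estimated correlation; 0.0609 without FLI replicate 6). Without control replicate 6 the median was 0.14, the adjusted p = 0.164 and no member was called adjusted over the list alone. Glycolysis had 24 of 25 members positive, median 1.27, with PGK1 at 886 ± 194 against 393 ± 270 (camera adjusted p = 0.000902; 0.995 with an estimated correlation; 0.0223 without control replicate 6, with a median of 0.55). Oxidative phosphorylation had 71 of 73 positive, median 1.70 (camera adjusted p = 0.00234; 0.995 with an estimated correlation; 0.457 without control replicate 6, with a median of 0.04). Control replicate 6, with 2995 reads, was at 0 for most genes, so medians with it exceed those without it. In place of 6 lists, 3 were called without it, 13 without control replicate 8, 12 without FLI replicate 7, and 11 without control replicate 5 or FLI replicate 5.

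Mitochondrially encoded genes had 4 of 13 positive, median -0.33 (camera adjusted p = 4.18e-09; 0.995 with an estimated correlation; 0.000932 without control replicate 6, with a median of -1.25). DNA methylation and histone-modifying enzymes had 24 of 32 members positive, median 0.65, while the test against other genes pointed down (camera adjusted p = 0.00945; 0.995 with an estimated correlation). Without control replicate 6 the median turned to -0.32 and the list was not called (0.0963). In the deep libraries 5 of them were lower adjusted over the list alone, including the H3K27 demethylase KDM6B at 4.88 ± 5.70 against 38.1 ± 18.6 and the acetyltransferase CREBBP at 26.8 ± 10.9 against 63.5 ± 12.3. KRT8, a keratin of the trophectoderm, was higher adjusted over the list alone, at 34520 ± 11470 against 15660 ± 7818 (19520 ± 1388 in deep controls), but not without control replicate 6. Without control replicate 6, S phase genes were called higher (0.0281; 0.726 with an estimated correlation), and adjusted over the list alone MYC was lower, at 4.67 ± 1.70 against 16.7 ± 9.64, APOE, a lipid carrier made by hypoblast, higher at 159 ± 69.1 against 53.5 ± 10.2, and the imprinted gene PEG3 lower at 6.59 ± 3.55 against 17.9 ± 6.72. ZIC2, at 0.643 ± 0.409 against 4.01 ± 0.740, and NLGN2, at 1.36 ± 0.934 against 7.0 ± 1.98, had the smallest p in deep libraries.

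Other lists were not called: receptors and ligands (0.0563, test down, median 0.51), S phase (0.0563), heat shock, genome activation, ribosome biogenesis and sperm transcripts (0.0743), blood cell markers (0.119), p53 (0.186), mitosis (0.291) and antioxidants (0.324). LIF-STAT3 response genes, FOXO targets, extracellular matrix, amino acid transport and hypoblast markers stood at 0.338, each with the test down and the median positive. Ribosomal proteins (0.401), cumulus markers (0.652), unfolded protein response (0.716), epiblast markers (0.823), fatty acid, cholesterol and imprinted genes and trophectoderm markers (0.952) and FGF-ERK response genes (0.979) were also uncalled.

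**Figure D2:**
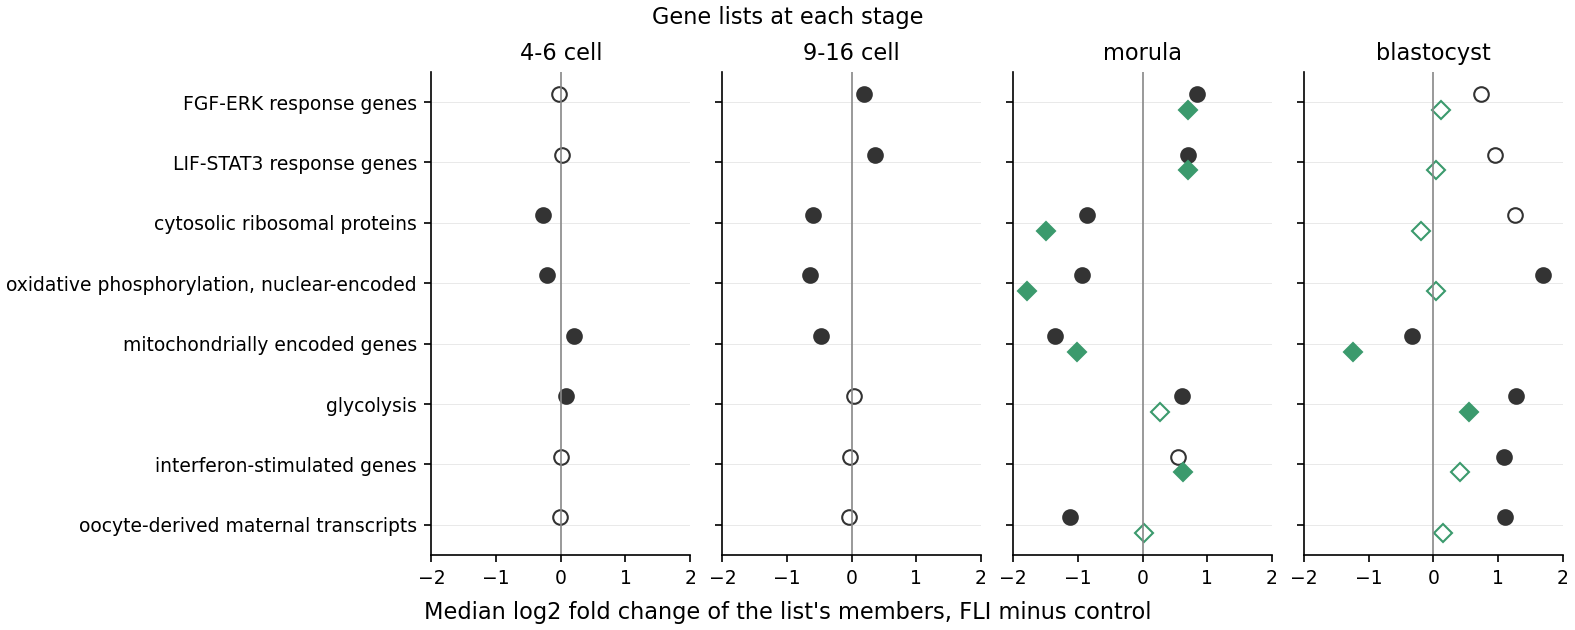
Median log2 fold change (FLI minus control) of 8 gene lists at the 4 stages; circles use all libraries, filled where the camera adjusted p is under 0.05, and diamonds leave out the library under 1 M reads. Maternal transcripts move from -1.12 to 0.03 at the morula stage when that library is left out.

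Whether the response to the cytokines differs between stages was tested as an interaction. No gene was called by limma, ND3 and IFI27 included, which stood out at single stages. It called 0 of 13515 genes for a difference among the 4 stages, with 234 at an unadjusted p under 0.05, and 0 for each pair of consecutive stages, with 10, 200 and 1332. On simulated data this fit recovered 0% of 8-fold changes for each pair with all libraries, so these counts exclude little. Without the shallow libraries it recovered 78.8%, 69.7% and 65.2%. These rates rest on the same spread for every gene and can be too high. edgeR called 0 in each (946, 131, 525 and 2311 at an unadjusted p under 0.05) and limma-voom called 0. DESeq2 called 13, 1, 23 and 230. Differences in the lists between stages were not tested. Without the shallow libraries limma still called 0, with 1127, 100, 745 and 3044 at an unadjusted p under 0.05, and without morula control replicate 7 or morula FLI replicate 7 it called 1 between morula and blastocyst.

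Control embryos at consecutive stages give the developmental background. Between the 4-6 cell and 9-16 cell stages, a pair of genome activation genes rose from near 0: KLF17, a pluripotency factor, from 0.185 ± 0.154 to 508 ± 302 CPM, and ZSCAN4, a marker of the activation, from 0.851 ± 0.726 to 97.3 ± 17.3 CPM. As lists, genome activation genes were higher (camera adjusted p = 1.12e-06) and maternal transcripts lower (camera adjusted p = 0.00219), and both calls ended with an estimated correlation (0.984). At the morula stage oocyte genes such as NLRP5 and NOBOX were nearly gone while the keratins KRT8 and KRT18, POU5F1 and 44 of 73 nuclear-encoded oxidative phosphorylation genes rose. Measures of library preparation differed between these control stages too, as given below. In blastocysts the trophectoderm genes KRT19 and PTGS2 rose steeply.

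**Figure D3:**
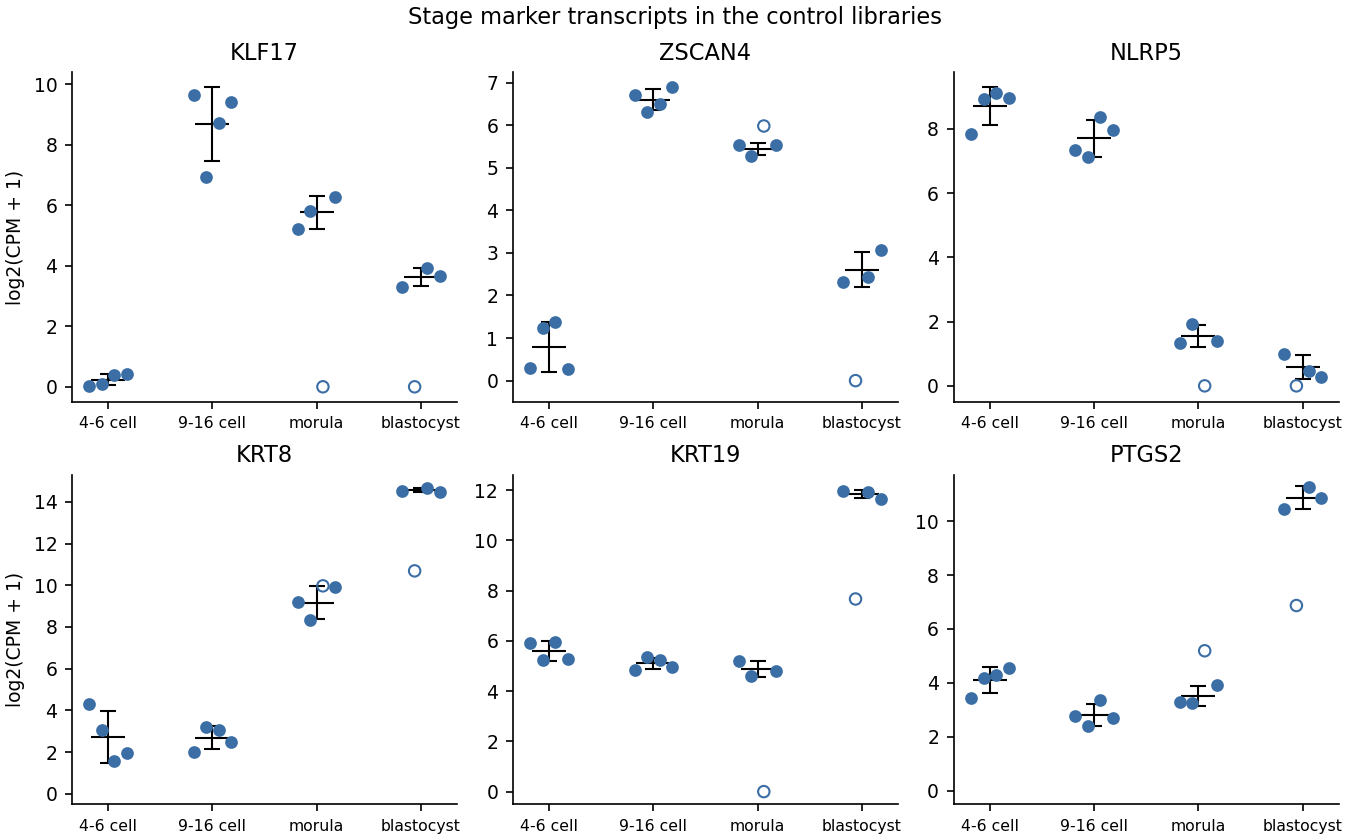
Levels of KLF17, ZSCAN4, NLRP5, KRT8, KRT19 and PTGS2 in each control library, as log2(CPM + 1), by stage; open circles are libraries under 1 M reads, and bars give mean ± SD of the others. KLF17 stands at 0.185 CPM on average at the 4-6 cell stage and at 508 CPM at the 9-16 cell stage.

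From the 4-6 cell to the 9-16 cell stage limma called 265 of 13561 genes, of which 262 rose. Besides KLF17 (chromosome 3, 101936564 to 101939528; log2 8.45, SE 1.18, adjusted p = 0.000243) the largest rises were those of AMIGO2 (358 ± 175 against 0.108 ± 0.135 CPM; log2 8.22), the histone variant H2AZ1 (1334 ± 731 against 5.08 ± 4.49; 7.90), the splicing factor TRA2B (7.63) and PNRC1 (7.61). TRIM50 fell from 22.7 ± 0.193 to 6.51 ± 4.76 CPM (log2 -1.83). Of 19 genome activation genes 15 had a positive fold change, median 1.49, with 2 called over all genes and 4 adjusted over the list alone (camera adjusted p = 1.12e-06; 0.984 with an estimated correlation, as for the other lists called between these stages). ZSCAN4 (log2 5.80, SE 0.69, adjusted p = 4.56e-05) and the epiblast factor PRDM14 (107 ± 53.7 against 2.52 ± 1.36 CPM; 4.92) rose. The hypoblast factors PDGFRA (40.1 ± 15.2 against 0.612 ± 0.605) and GATA6 (31.7 ± 21.5 against 0.390 ± 0.464) rose adjusted over the list alone, and of 20 hypoblast markers 15 were positive (camera adjusted p = 0.0477; 0.984 with an estimated correlation; 0.119 without shallow libraries; 0.0507 to 0.085 without 4-6 cell replicates 8 or 9, 9-16 cell replicates 11 or 13, or morula replicates 4 or 7). Ribosomal proteins had 75 of 76 positive, median 1.43 (2.6e-10), and mitochondrially encoded genes a median of 1.10 (0.0102; 0.0518 without 4-6 cell replicate 9 and 0.0505 without 9-16 cell replicate 11). No member of either was called, and both list calls ended with an estimated correlation (0.984). Cumulus markers were called higher at 0.0477 (0.984 with an estimated correlation). They were not at 0.248 without shallow libraries, nor without any of those 6 libraries or blastocyst replicates 6 or 8 (0.0507 to 0.195). The calls of H2AZ1, TRIM50 and PRDM14 ended without single controls too, for H2AZ1 at adjusted p-values of 0.0511 to 0.0609 without 4-6 cell replicate 9 or 9-16 cell replicates 10 or 11, for PRDM14 at 0.0643 to 0.129 without any 4-6 or 9-16 cell control, and for TRIM50 at 0.062 to 0.2 without any control but 9-16 cell replicate 12 and both shallow ones.

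Of 38 maternal transcripts, 6 had a positive fold change and the median was -0.57 (camera adjusted p = 0.00219; 0.984 with an estimated correlation; 0.000495 without shallow libraries). Without the shallow libraries 13 members fell and 2 rose adjusted over the list alone, among them NLRP2 (60.7 ± 14.9 against 245 ± 36.2 CPM), the meiotic kinase WEE2 (414 ± 51.6 against 1085 ± 147) and ZAR1 (312 ± 53.8 against 869 ± 96.1). Because all 16 controls share an estimate of the spread, blastocyst control replicate 6 and morula control replicate 4 limit the calls. Without both, limma called 2922 genes (1846 rose, 1076 fell), without blastocyst control replicate 6 alone 1060 and without morula control replicate 4 alone 441. It called 161 to 175 without 4-6 cell control replicates 7, 8 or 9 or 9-16 cell control replicates 10 or 13, and among libraries with at least 0.2% rRNA fragments 3782.

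From the 9-16 cell stage to the morula limma called 3314 genes (967 rose, 2347 fell). CSTB, a protease inhibitor (chromosome 1, 143819489 to 143823793), rose from 1.34 ± 2.0 to 2444 ± 2083 CPM (log2 9.53, SE 1.54, adjusted p = 0.00023), and PPP1R14A (8.38), GCSH of glycine cleavage (7.61), the tight junction gene CLDN6 (16.2 ± 8.01 to 3048 ± 1419; 7.42) and S100A14 (7.28) followed. The largest falls were ACCSL (2909 ± 802 to 72.4 ± 135 CPM; log2 -7.54, SE 1.09, adjusted p = 8.68e-05), DIRAS2 (-7.17), SELENBP1 (-7.13), the oocyte importin KPNA7 (-6.87) and RGS16 (-6.79). POU5F1, the core pluripotency factor, rose from 68.0 ± 19.3 to 1209 ± 371 CPM (log2 4.11), OTX2 (3.89) and TFCP2L1 (3.78) rose too, and KLF17 fell (-4.36). The keratins KRT18 (2.86 ± 0.851 to 529 ± 231; 7.02) and KRT8 (6.68) and the tight junction gene CLDN4 (5.33) rose.

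Of 38 maternal transcripts none had a positive fold change, the median was -5.36 and 32 fell, over all genes and adjusted over the list alone (camera adjusted p = 3.62e-16; 0.994 with an estimated correlation, as for the other 7 lists called between these stages), with NLRP5 from 220 ± 87.8 to 1.49 ± 1.16 CPM (log2 -6.54), PADI6 (-6.03) and NOBOX (-6.01). All 73 oxidative phosphorylation genes were positive, median 4.39, with 44 called and 52 adjusted over the list alone (camera adjusted p = 7.85e-22), and all 76 ribosomal protein genes, median 3.49, with 36 called and 55 adjusted over the list alone (1.96e-19). Both list calls ended with an estimated correlation (0.994). Mitochondrially encoded genes had a median of 2.46 and no member called (0.000784; 0.994 with an estimated correlation). Of 20 hypoblast markers 5 rose, such as FN1 (5.91) and SPARC (5.43), and 3 fell (camera adjusted p = 0.0042). FGF-ERK response genes had a median of -1.81, and 12 of 28 fell (0.00884; 0.0568 without shallow libraries). Fatty acid genes (0.036; 0.0712 without 9-16 cell replicate 11 and 0.0914 without morula replicate 7) were called higher. Cumulus markers were called lower, median -1.48, with 6 members falling (0.049; 0.0513 to 0.108 without 9-16 cell replicates 11 or 13, morula replicates 1, 3 or 7, or blastocyst replicates 6, 7 or 8). All 8 calls ended with an estimated correlation (0.994). Without the shallow libraries limma called 9675 genes (4942 rose, 4733 fell) and the maternal list had an adjusted p = 0.0211 with an estimated correlation. Without blastocyst control replicate 6 alone limma called 7086, and 10220 among libraries with at least 0.2% rRNA fragments. With RLE scaling it called 6086, of which 656 rose.

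From morula to blastocyst limma called 131 genes (26 rose, 105 fell). KRT19, a keratin of the trophectoderm (chromosome 19, 41731625 to 41735635), rose from 21.7 ± 15.5 to 2853 ± 1798 CPM (log2 7.15, SE 1.15, adjusted p = 0.00339), as did PLS1, a bundler of microvilli (6.55), DPEP1 (6.18), the prostaglandin synthase PTGS2 (16.8 ± 12.7 to 1463 ± 1006; 5.94) and PSAT1 of serine synthesis (4.51). ND3 (-6.28), the linker histones H1-2 (-6.11) and H1-4 (-5.39), CSF1R (59.98 ± 12.5 to 0.418 ± 0.388; -5.44) and H2BC15 (-5.21) fell most. ZSCAN4 (47.5 ± 10.4 to 3.94 ± 3.03; -3.62), CCNA1 (-3.68) and NR5A2 (-3.11) fell, and 19 genome activation genes had a median of -2.07 (camera adjusted p = 0.00286; 0.948 with an estimated correlation). Without morula control replicates 1 or 3 the calls of ND3, H1-4, H2BC15, CCNA1 and NR5A2 ended, at adjusted p-values of 0.0689 to 0.128. All but that of H2BC15 ended without blastocyst control replicate 7 (0.0561 to 0.126) as well, and those of ND3 and NR5A2 without others (0.0505 to 0.0868).

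Of 25 trophectoderm markers 18 had a positive fold change, median 1.40, with 3 called and 5 adjusted over the list alone, among them KRT8 (724 ± 326 to 18470 ± 11280 CPM; log2 4.22, a call that ended, at adjusted p-values of 0.0659 to 0.166, without any control but 4-6 cell replicate 6 and both shallow ones; camera adjusted p = 3.24e-10; 0.948 with an estimated correlation, as for the other 10 lists called between these stages). Of 24 cholesterol genes 19 were positive, median 1.31 (2.62e-08), and of 28 unfolded protein response genes 18, median 0.80 (9.79e-05), with glycolysis at a median of 0.12 (0.00105). These 3 calls ended with an estimated correlation (0.948), and with all libraries 0, 1 and 0 of their members were called over all genes. Ribosomal proteins (median -2.83; 1.49e-10), maternal transcripts (-2.46; 1.96e-08), ribosome biogenesis (9.79e-05), oxidative phosphorylation (9.96e-05), mitosis (0.000365; 0.0584 without morula replicate 4) and mitochondrially encoded genes (0.00105; 0.0744 without morula replicate 4) were called lower. Their calls ended with an estimated correlation too (0.948). Without the shallow libraries limma called 3817 genes (2202 rose, 1615 fell), and adjusted over the list alone 19 trophectoderm markers rose and 1 fell (adjusted p = 0.00655 with an estimated correlation), 23 cholesterol genes rose (adjusted p = 0.00655 with an estimated correlation), with HMGCS1 from 37.2 ± 2.13 to 500 ± 68.0 CPM. In those libraries 17 unfolded protein response genes rose and 1 fell (adjusted p = 0.00193 with an estimated correlation), and 13 glycolysis genes rose and 2 fell (adjusted p = 0.0141 with an estimated correlation), with LDHA from 49.4 ± 7.81 to 660 ± 106. Without blastocyst control replicate 6 alone limma called 1791 genes, and without morula control replicate 4 alone 497. It called 63 to 74 without morula control replicates 1 or 3 or blastocyst control replicate 7, and among libraries with at least 0.2% rRNA fragments 4815.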

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

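Of the tests in this part, those of the cytokine response in matched pairs of libraries and of interferon tau were written before their result was seen, while those of library preparation and the counts of other splits were written after the result was seen. Libraries or values that lie far from the other 3 of their group were found in 17 of the 88 groups checked, and chance gives about 1 in 20 by the 95% critical value of the rule. Several groups are measures of the same library, and some genes were named for extreme values, so the 2 rates are not a test.

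Blastocyst control replicate 6 had 1061 genes detected at 1 CPM, against 12303 to 12870 in the other controls. At the 4-6 cell stage replicate 6 stood apart in both groups. FLI replicate 6 had 89.2 M reads and control replicate 6 had 82.9 M, against 12.4 to 22.6 M in the others. The share of reads in the 100 most abundant genes was 22.6% in FLI replicate 6 and 25.5% in control replicate 6, against 16.8% to 17.0%. Short minus long genes stood at -0.0500 on the log2 scale in FLI replicate 6, against -1.82 to -1.71 in the other FLI libraries. The same measure was -0.34 in 9-16 cell control replicate 11, against -1.43 to -1.31. COX1 was 1134 in 4-6 cell FLI replicate 6, GIMAP4 was 3.95 in 4-6 cell control replicate 7, ZMYND15 was 0.874 in 9-16 cell control replicate 11, and H2AC12 was 29.8 in morula FLI replicate 6. Fragments of rRNA took 1.87% of reads in morula control replicate 7, against 0.0378% to 0.294% in the other controls. In blastocyst FLI replicate 8 they took 0.387%, against 0.000249% to 0.00428% in the other FLI libraries, and mitochondrially encoded genes took 5.58%, against 0.646% to 1.15%. That library also held 3816 of ENSBTAG00000051364 (48.7 to 100 in the others) and 4678 of bta-mir-2887-2, the symbol by which rRNA fragments are counted here. IFI27 was 0.918 in blastocyst control replicate 8, against 0 to 0.122 in the other controls. The interaction of treatment with stage gave 0 genes with limma, edgeR and limma-voom and 13 with DESeq2 among the 4 stages, as above.

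The first pattern is the lower level of ribosomal protein and respiratory chain transcripts as lists in FLI morulae, with higher FGF-ERK and LIF-STAT3 response lists, calls that end with an estimated correlation. Across 11249 genes, the difference of the 7 deep morula libraries had a Pearson correlation of -0.821 (Spearman -0.814) with the difference between the replicate 6 libraries and the others at the 4-6 cell stage, a difference that holds 1 FLI and 1 control library. A difference in library preparation, which retains short transcripts to a varying degree, may therefore account for much of the pattern; genes are not independent replicates. As a test of a response to the cytokines, FLI replicate 6 and control replicate 7, which match in short minus long genes, were set against the other deep libraries, and their differences had a correlation of 0.049 across 13254 genes. That lies between the bounds set in advance, so a response of the embryos cannot be told apart from none here. The higher ETV4 and DUSP5 of the deep libraries, called only adjusted over the list alone, stay open.

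The second pattern is the set of differences in blastocysts, such as lower KDM6B and MYC and higher APOE with FLI, adjusted over their lists alone in the deep libraries. Across 12249 genes, the difference of the 7 deep blastocyst libraries had a correlation of 0.804 (Spearman 0.743) with the difference between FLI replicate 7 and the other FLI libraries at the morula stage, in which treatment is constant. Library preparation, or another difference between pools of the same treatment, may thus account for much of this pattern too. The matched pair of FLI replicate 8 and control replicate 5 differed along with the other libraries, with a correlation of 0.183 across 13029 genes (0.126 across 12249 genes with the library difference removed), as a response to the cytokines would need. Both explanations stay open, and the pair had a correlation of 0.141 with the library difference itself.

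The third pattern is the higher level of interferon-stimulated transcripts in FLI blastocysts, with IFI27 called over all genes, ISG15 and IFI6 only adjusted over the list alone, and a list call that ends with an estimated correlation; none of these stands without the shallow control, and that of IFI27 ends without any of 7 libraries. In the difference between FLI replicate 7 and the other FLI morulae, the median of this list lay at percentile 98.44 of 10000 random lists of similar level, but this sets 1 pool against 3, and a pool with a stronger interferon response would give the same, so library preparation cannot be told apart from that. The trophectoderm's own signal, interferon tau, was tested as a biological source. The mean log2 level of 5 interferon tau genes was 1.89 ± 0.908 in FLI (n = 4) and 2.25 ± 0.407 in deep controls (n = 3), a difference of -0.357 with an SE of 0.511. The spread is too wide to exclude a rise, and since IFI27 stood at 17.7 and 13.5 in FLI replicates 6 and 7 but at 2.30 and 0.166 in the others, a difference between single pools stays open.

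Other splits of the same libraries into groups of 4 show which counts arise without regard to treatment. For genes at the 4-6 cell, 9-16 cell and morula stages the real count was 0, so all 35 of 35 splits gave as many by construction, which says nothing about chance, and the highest other count was 0. For lists 13 of 35 splits gave at least the real 5 at the 4-6 cell stage (highest other 9), 18 at least the real 6 at the 9-16 cell stage (highest other 9) and 7 at least the real 10 at the morula stage (highest other 14). At the 4-6 cell stage, of the 8 splits that part all 4 pairs of replicate numbers, 4 gave at least 5 lists (highest other 9), and splits that part fewer gave up to 8. At the blastocyst stage 3 splits gave at least the real 3 genes (highest other 9, with controls 5, 7 and 8 and FLI replicate 8 on 1 side) and 13 at least the real 6 lists (highest other 9). Chance cannot be excluded for the lists of these stages or for the blastocyst genes. Without the shallow library the real count was 0 at both stages, and 35 of 35 splits gave as many by construction. The highest other was 2223 genes in morulae, for control replicate 7 and FLI replicates 2, 4 and 6 against the rest, and 992 in blastocysts, for controls 5, 7 and 8 with FLI replicate 8, so the libraries have a structure other than treatment. Both splits part libraries with higher from those with lower rRNA-fragment shares. For the interactions the real counts were 0, so all 100 of 100 splits drawn gave as many by construction, with highest others of 5, 0, 6 and 53.

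In controls chance can be excluded for genes from the 4-6 to the 9-16 cell stage (1 of 35 splits, real 265, highest other 0). It can be too for genes from there to the morula (1 of 35, real 3314, highest other 837). For lists of that step (preset correlation, all controls) the real 8 led the highest other, 7, by 1 list (1 of 35). Their count was 6 (9-16 cell control replicate 11 or morula control replicate 7) to 9 (blastocyst control replicate 6) with single controls left out. It was 7 without the shallow libraries and 0 with an estimated correlation, so chance cannot be excluded for them. It cannot be excluded for lists from the 4-6 to the 9-16 cell stage (18 of 35; real 6, highest other 9), nor for genes (6 of 35; real 131, highest other 1608) and lists (5 of 35; real 11, highest other 11) from morula to blastocyst, where both stages hold a shallow library.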

How the results depend on the processing

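After the values were seen to be scaled, limma replaced the edgeR quasi-likelihood test, the planned main test, which became an alternative on recovered reads. Alternatives that leave out shallow libraries, keep only libraries with at least 0.2% rRNA fragments or add covariates were chosen after the data were seen. So were those that use other forms of edgeR, use fry between control stages or recompute the scaling. The others were planned as alternatives. Of these, 475 for the main results and 2344 for named genes and lists kept direction and side of the threshold, while 35 and 285 were weaker, 29 and 61 stronger, 22 and 17 moved, and 0 and 5 reversed. Depth limits the morula and blastocyst comparisons, where a count of 0 in the shallow control allows 36.0 and 1002 CPM. Unless fewer libraries are named, the cause of a change was not tested.

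For genes called between FLI and control, the edgeR likelihood ratio test gave 8 at the 9-16 cell stage (limma 0), 864 in morulae (2062 without the shallow library; limma 0) and 336 in blastocysts (379 without it; limma 3). DESeq2 gave 579 in morulae (2486 without the shallow library) and 466 in blastocysts without it, and edgeR 629 in morulae without it. In blastocysts the count of 3 became 0 with a pseudocount of 0.1, limma-voom, DESeq2, edgeR and all 32 libraries in 1 fit. It was also 0 without the shallow library in limma and edgeR. Fits with either library score as a covariate gave 0 too, but they left out the shallow library as well. Their 0 can therefore not be put down to the score. With no filter it was 6. Leaving out 1 library gave 0 (control replicate 6) to 4 (FLI replicate 8), with 1 without control replicate 7, control replicate 8 or FLI replicate 5. Without the shallow library and a second one, blastocysts gave 0 to 386 genes, with 177 without control replicate 5 and 386 without FLI replicate 8, and morulae 0 to 4620, the latter without control replicate 7 (see the limit above); fewer libraries were then tested. The 4-6 cell, 9-16 cell and morula counts of 0 by limma stayed 0 with each single library left out.

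Replicate numbers pair the libraries at the 4-6 cell stage. The block there changed no call but that of hypoblast markers (0.0524). At the other stages libraries share only a number. Correlations within a number were 0.285, 0.0747, 0.143 and 0.0628 at the 9-16 cell stage (only replicate 10 correlated best with its own number), 0.103 and -0.295 for morula replicates 4 and 7, and -0.498, -0.117, 0.179 and -0.0372 in blastocysts (only replicate 7 did). With the replicate number as a block limma called 18 genes in morulae (16 higher with FLI), with 1 residual degree of freedom, and 1 in blastocysts (0 higher), and edgeR with the block 73 (0 higher) and 111 (30 higher). In morulae oxidative phosphorylation then turned up, uncalled (0.98), and ribosomal proteins and FGF-ERK (both 0.318), LIF-STAT3 (0.736) and amino acid transport (0.182) were uncalled.

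The interaction gave 13, 1, 23 and 230 genes with DESeq2. Between 9-16 cell and morula it gave 1 with no filter and 1 with at least 1 in 4 libraries. With single libraries left out it gave 0 to 1 between morula and blastocyst.

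For genes called between control stages the values follow in the order of development. A pseudocount of 0.1 gave 93, 1331 and 19, edgeR 1659, 8503 and 2582, limma-voom 2007, 8872 and 2955, and DESeq2 2579, 9401 and 3006. Without the shallow libraries limma gave 2922, 9675 and 3817, and among libraries with at least 0.2% rRNA fragments 3782, 10220 and 4815. RLE scaling gave 458 and 6086 for the first and the second. An adjusted p under 0.10 gave 251 from morula to blastocyst. With single libraries left out the counts were 161 (4-6 cell control replicate 9) to 1060, 2217 (9-16 cell control replicate 13) to 7086, and 63 (morula control replicate 1) to 1791, each highest without blastocyst control replicate 6.

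For lists called, an estimated correlation gave 0 in all 7 comparisons, and fry gave 0 in all but the controls from the 9-16 cell stage to the morula, which had 1. Without shallow libraries and with an estimated correlation the counts were 0 in morulae, 0 in blastocysts, and 0, 1 and 4 between control stages. Without the shallow library 3 lists were called in blastocysts. Among libraries with at least 0.2% rRNA fragments 1 was called at the 9-16 cell stage and 15 in blastocysts, where that set holds 1 FLI library, replicate 8, and so is no test of the treatment. With single libraries left out the counts were 2 (FLI replicate 9) to 6 (control replicate 6) at the 4-6 cell stage, 1 (control replicate 11) to 7 (control replicate 12) at the 9-16 cell stage, 3 (control replicate 6) to 13 (control replicate 8) in blastocysts, and 3 (4-6 cell control replicate 9) to 8 (blastocyst control replicate 6) for controls from the 4-6 to the 9-16 cell stage. With single libraries left out at the 4-6 cell stage, the adjusted p of oxidative phosphorylation was 4.8e-10 (FLI replicate 6) to 0.815 (FLI replicate 7), and that of ribosomal proteins 3.46e-17 (control replicate 7) to 0.375 (FLI replicate 7). Both reversed without control replicate 6, and the former without FLI replicate 7, as given above. In blastocysts the sign of mitochondrially encoded genes (0.0602) and interferon-stimulated genes (0.232) differed among libraries with at least 0.2% rRNA fragments, which gives the value of FLI replicate 8 alone, and it reversed for DNA methylation and histone enzymes with fry (0.646).

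For measures per library, FLI minus control, genes detected at 5 CPM differed by -2.5 at the 4-6 cell stage and 35.8 at the 9-16 cell stage, and at 1 count by 211 at the 9-16 cell stage. With single libraries left out, genes detected differed by -72.8 (control replicate 13) to 18.2 (control replicate 11) at the 9-16 cell stage and by -279 (control replicate 6) to 3658 (control replicate 8) in blastocysts. The mitochondrial share at the 4-6 cell stage differed by -0.0630 (FLI replicate 6) to 0.242 percentage points (control replicate 6). The share of the 100 most abundant genes differed by -2.27 to 1.31 points at the 4-6 cell stage, without the same libraries, and by -1.57 (control replicate 10) to 0.265 (control replicate 11) at the 9-16 cell stage, and that of the 20 most abundant by 0.397 in morulae. Total reads differed by -14.6 to 19.98 M at the 4-6 cell stage without FLI and control replicate 6, by -3.16 (FLI replicate 13) to 12.1 M (control replicate 11) at the 9-16 cell stage, and by -27.3 (FLI replicate 7) to 6.86 M (FLI replicate 4) in morulae.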

Other observations

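No explanation is offered in this part, and its values were chosen after the other results were seen, except for the receptors and ligands of the cytokines, a list fixed before. Levels of the receptors of the added cytokines in the deep control libraries are given here as values, not tested between stages. FGFR1 was at 8.83, 7.05, 6.88 and 3.94 at the 4 stages in order (means, n = 4, 4, 3 and 3). FGFR3 was at 0.216, 8.40, 39.8 and 89.8, and FGFR4 at 1.25 ± 1.14 at the 9-16 cell stage, 146 ± 82.8 in morulae and 81.4 in blastocysts. LIFR was at 14.0, 11.99, 6.76 and 1.67, while its partner IL6ST was at 3.56 ± 1.82 and 3.86 ± 0.609 before the morula, 46.5 ± 4.54 in morulae and 103 ± 9.67 in blastocysts. With FLI, IL6ST was at 32.2 ± 4.28 in morulae and 81.5 ± 15.3 in blastocysts. IGF1R was at 115 ± 60.8 and 117 ± 49.7 at the early stages, then at 13.1 ± 9.88 in morulae and 15.8 ± 7.49 in blastocysts. IGF2R, which clears IGF2, was between 47.7 and 103 in controls.

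Of the ligands, the embryo's own FGF2 was at 19.3 ± 4.30 and 12.2 ± 1.76 at the early stages and at 0.306 and 0.432 later. FGF4, made by epiblast, was at 8.94 ± 1.27 in control morulae and 2.76 ± 0.487 in control blastocysts. LIF (0.251 at the 4-6 cell stage), IGF1 (0.602 at the 9-16 cell stage) and IGF2 (0.219 to 1.22) were low. Of the IGF binding proteins, IGFBP3 was at 208 ± 29.9 at the 4-6 cell stage and IGFBP2 at 299 ± 192 in control and 899 ± 623 in FLI morulae. These values come from separate tables per stage.

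The authors' deposited table lists genes at a false discovery rate under 0.05 in numbers of 0, 13, 1856 and 744 at the 4 stages in order. Of the morula genes in the authors' deposited table, 580 are higher with FLI and 1276 in controls, and of the blastocyst genes 199 and 545. Of these, 1024 morula and 698 blastocyst genes had 0 reads in the shallow library, as had 8904 of all 17446 and 15290 of all 16351 genes listed there, so the shares are close to those of all genes. At the 9-16 cell stage the authors' deposited table has TENT5A higher with FLI (log2, control minus FLI, -1.26; false discovery rate 0.0400) and ISG15 lower (2.35; 0.0400). By the same naming rule 752 morula genes of the authors' deposited table qualify, with CAPN14, a calpain (-5.95), NLRC5, a regulator of MHC class I (-2.62), SLC12A8 (-2.44) and VRTN (-2.20) among the largest rises with FLI, and ND3 (3.14), DAPL1 (3.04), TMSB4 (2.97) and LYZ3 (2.95) among the largest falls. At the blastocyst stage 387 qualify in the authors' deposited table, with TUBAL3 (-4.23), ITPKA, an inositol phosphate kinase (-2.63), and PAX9 (-1.84) among the rises with FLI, and DVL1 of WNT signalling (4.38), KDM6B (3.89), EMILIN2 (3.87) and MAPK3, which encodes ERK1 (3.25), among the falls. The edgeR likelihood ratio test on recovered reads called 8, 864 and 336 genes at the last 3 stages, of which 6, 792 and 334 are among those of the authors' deposited table.

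Across genes, which are not independent replicates, the morula and blastocyst differences between FLI and control had a correlation of -0.082. The 9-16 cell difference had a correlation of -0.726 with the difference between the replicate 6 libraries and the others at the 4-6 cell stage, and transcript length had a Spearman correlation of 0.473 with the morula difference and -0.295 with the blastocyst difference. With a library score as a covariate limma called 0 genes in morulae (851 at an unadjusted p under 0.05) and in blastocysts (3697 and 254).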
